A study of Homo sapiens with 12 samples.

How the data were processed

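RNA from U87MG, a human glioblastoma cell line, was measured after 24 hours in 1 of 4 conditions: normoxia at pH 7.4, normoxia with acidosis at pH 6.0, hypoxia with 1% oxygen at pH 7.4, and hypoxia with acidosis. No oxygen percentage is given for normoxia in the sources used here. Lysates were separated by ribosome density, and RNA was sequenced from 3 fractions, called monosome (free RNA and RNA with a single ribosome), oligosome and polysome. The 12 libraries are 1 per condition and fraction. With no replicates, no difference between conditions has a replicate check, no test was run and no p-value is given.

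Libraries were made with a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq, STAR 2.5.0, Cufflinks 2.2.1, Cuffnorm and the build GRCh38, without saying what each was used for. The annotation and the normalization method of Cuffnorm are not given in the sources used here. The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the size of the library) for 55598 assembled loci, of which 4268 name several genes and 2419 name none. The summed FPKM ran from 372410 (normoxia with acidosis, polysome) to 2164000 (hypoxia with acidosis, monosome). If FPKM was divided by the library's total, a group of very abundant transcripts in 1 library lowers the FPKM of other loci there.

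Per the file headers, the authors also deposited a signal, the FPKM multiplied by 1 factor per library for its RNA concentration, with translation efficiencies and totals computed from it. The gene names beside that signal matched the names beside the FPKM on 1 of 53262 lines, while its values followed the FPKM of the same line on 21883 of 21883 nonzero lines in the normoxia polysome library (tolerance 1e-06). The authors' total for hypoxia with acidosis equalled its monosome and oligosome signal plus the polysome signal of hypoxia at pH 7.4 on 53262 of 53262 lines. For these reasons the names, efficiencies and totals of that part of the deposited table were not used. The FPKM per locus and the 12 factors recovered from the scaled columns were used.

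Steady-state mRNA was defined, after the series design, over all fractions: it was the log2 of the mean FPKM of the 3 fractions plus 1, with fractions weighted by their RNA factors within a condition. Translation efficiency (TE) was the log2 of polysome FPKM plus 1 over monosome FPKM plus 1, and a TE ratio is that quotient before the log. The pseudocount of 1 understates changes of low loci. It also draws the TE ratio of a low level toward 1, so a locus low in 1 condition alone can change in TE by this. Small RNA loci (4747) were left out, and 12194 loci with a mean FPKM of at least 1 over the 12 libraries were compared, of which 8945 name 1 gene. A change is the difference between 2 conditions minus the median difference of the compared loci, so it is relative to the median locus.

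Acidosis was measured in 2 pairs of conditions that share no library (in normoxia and in hypoxia), and hypoxia likewise (at pH 7.4 and at pH 6.0). The effect of a factor is the mean of its 2 pairs. A locus was called higher or lower in steady-state mRNA when it passed 2-fold in both pairs and went the same way in each fraction, and in TE when it passed 1.5-fold in both pairs. Hypoxia with acidosis against normoxia is a single comparison with the same thresholds, and for steady-state mRNA the same direction in each fraction. The loci expected to pass in both pairs if the pairs were unrelated were computed from the numbers that passed in each pair. This takes every locus as equally likely to pass. Loci with a larger error pass more often in both pairs, so the expected number is too low by an unknown amount.

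The definitions, thresholds, gene lists, naming rule and the alternatives not named as added later were fixed before the data were examined. The naming rule took the 10 largest mean changes each way per effect (5 each way for hypoxia with acidosis), up to 4 members per gene list, and 12 genes tied to hypoxia, translation and sterol synthesis. Small RNAs, clone names and loci naming several genes were left out of naming. Some genes that the rule picked are not reported here. For each list of genes, the median change is given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Of the 26 lists, 1 (mRNAs of the mitochondrial genome) had 0 of 13 genes measured, since those genes lie in loci that name several genes, and 1 holds markers of other cell types, for which levels alone were read.

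Some choices were made after values had been seen. A gene name carried by several compared loci was left out of the lists. Loci whose monosome FPKM was at least 10 times their polysome FPKM in normoxia are called monosome-confined (1134 loci), and are named as such where they appear. Several alternatives and some tests of explanations were also added then, as stated beside their values.

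FPKM carries no total counts. Relative depth was read from the most frequent ratio of low loci between libraries, which a minority of these loci share (from 352 of 4140 to 719 of 4600 loci compared), and the number of fragments from the smallest steps of low loci in genes with 1 transcript length. Estimated depth ran from 0.626 (hypoxia with acidosis, monosome) to 2.51 (normoxia with acidosis, polysome) times that of the normoxia monosome library. A transcript of 2 kb at 10 FPKM then holds about 95.2 fragments in the first of these and 382 in the second. The fragment numbers are estimates that assume the annotated lengths. For a transcript of 2 kb, the counting error (SE) of a log2 TE difference between hypoxia with acidosis and normoxia was 0.70 at 1 FPKM, 0.22 at 10 FPKM and 0.07 at 100 FPKM. These errors cover counting only, not the spread between cultures.

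The calling rule was tested on simulated fragments with counting error alone and 200 altered loci per comparison. For steady-state mRNA, loci altered 2-fold were called in 0% of cases for acidosis and 6% for hypoxia, so a 2-fold change mostly goes uncalled. Loci altered 3-fold were called in 72% of cases for acidosis and 88% for hypoxia, and loci altered 4-fold in 92% and 88%. For TE, the shares were 62% and 64% at 2-fold, 86% and 86% at 3-fold, and 90% and 86% at 4-fold. With no effect, 0 loci were called for steady-state mRNA in either effect, 31 higher and 33 lower for TE with acidosis, and 44 higher and 33 lower for TE with hypoxia. In the single comparison of hypoxia with acidosis against normoxia, 454 higher and 382 lower loci were called for TE with no effect. The acidosis effects were 2-fold apart between oxygen levels for 392 loci in TE and 4 in steady-state mRNA with no effect. These counts leave out differences between cultures and gradients.

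Alternatives covered the pseudocount (0.1), the filter on low values (none, or a mean FPKM of at least 5), the centring (none, or a trimmed mean), small RNA loci, fraction weights, leaving out each fraction, and other TE ratios. The authors' RNA scaling without centring was among those added later. Under it the median log2 TE change of the compared loci was 0.31 for acidosis in normoxia, -0.06 for acidosis in hypoxia, -0.39 for hypoxia at pH 7.4 and -0.73 for hypoxia at pH 6.0. The median log2 steady-state change under it was -0.06, 0.00, -0.36 and -0.30 for the same comparisons. Changes are reported relative to these medians unless this scaling is named.

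Gene positions are those of GENCODE release 29 on GRCh38, matched by gene name and counted from 1. They give the whole gene, with exons and introns. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.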

Results

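Translation efficiency and steady-state mRNA were profiled in U87MG glioblastoma cells kept for 24 hours in normoxia, in acidosis at pH 6.0, in hypoxia with 1% oxygen, or in hypoxia and acidosis together. Each condition gave 3 libraries from a ribosome density gradient (monosome, oligosome and polysome), 12 in all, with 1 library per condition and fraction. Steady-state mRNA and TE were both computed from these fractions, so they are not independent, and amounts of mRNA per cell were not measured. No difference between conditions has a replicate check, so sizes are given without p-values.

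The RNA factors that the authors used for scaling put 3.597 times as much RNA in the polysome as in the monosome fraction in normoxia. The polysome to monosome ratio was 4.89 in normoxia with acidosis, 2.92 in hypoxia and 2.74 in hypoxia with acidosis. The oligosome fraction differed more between conditions, at 2.46, 4.47, 2.25 and 1.14 times the monosome fraction in the same order. Summed over fractions, the factors were 0.981 of the normoxia total with acidosis, 0.809 with hypoxia and 0.712 with both.

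**Figure D1:**
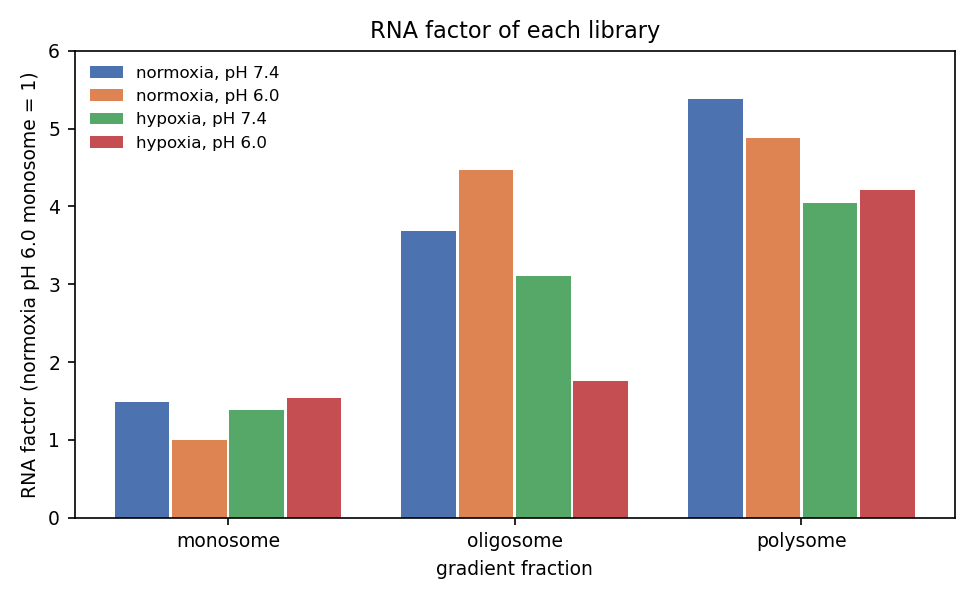
RNA factor of each of the 12 libraries (bars, in units of the normoxia pH 6.0 monosome library) by gradient fraction and condition. The oligosome bar of hypoxia with acidosis is 1.76, against 3.68 in normoxia.

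Estimated depth ran from 0.626 to 2.51 times that of the normoxia monosome library, and the 4 monosome libraries were the shallowest. The 100 most abundant loci held 30.6% of the summed FPKM in the polysome library of normoxia with acidosis and 71.2% in the monosome library of hypoxia with acidosis. Of 24 genes that mark other cell types, 2 reached a mean FPKM of 1: SNAP25, a neuronal synaptic protein (4.50 FPKM), and EPCAM, an epithelial adhesion protein (1.26 FPKM).

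With acidosis, the median steady-state change of ATF4 stress response genes lay above 0 and that of DNA replication genes below 0, with 2 of 22 and 0 of 28 genes called. RRAD, which encodes a Ras-related GTPase (GRCh38 chromosome 16, 66921679 to 66925644), had the largest mean log2 change among named genes (2.81), with an aggregate of 2.90 FPKM in normoxia and 52.98 FPKM with acidosis, and of 6.05 FPKM in hypoxia and 26.3 FPKM with acidosis. ASNS, asparagine synthetase (chromosome 7, 97852118 to 97872542), was 4.25-fold higher on average, and TXNIP, an inhibitor of thioredoxin (chromosome 1, 145992435 to 145996600), 5.05-fold. HNRNPAB, an RNA-binding protein gene (chromosome 5, 178204507 to 178211163), was lower in both pairs (log2 -1.08 in normoxia and -3.34 in hypoxia).

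Other genes with higher mRNA were SAMD11 (log2 2.35), ALDH3B1 (2.06), CSRNP3 (1.998) and the names C1orf213, CECR5-AS1 and C8orf56 (2.44, 2.198 and 2.06). With lower mRNA stood DKK1, a secreted Wnt inhibitor (-1.73), CHORDC1 (-1.64), MICALL1 (-1.60), IL1RN, the interleukin 1 receptor antagonist (-1.52), ZNF367 (-1.39) and GINS3 (-1.39). RANBP3L (-2.08) was monosome-confined.

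Among 22 measured ATF4 stress response genes, 2 were called higher and 0 lower, and the list median was 0.35 (percentile 99.4). Its largest members were ASNS (2.09), the amino acid transporter gene SLC7A5 (1.56), PHGDH of serine synthesis (1.23) and MTHFD2 of mitochondrial folate metabolism (1.15). In the p53 target list 1 of 18 genes was called, CDKN1A, the cell cycle inhibitor p21 (1.84), with list medians of 0.17 for the mean of the pairs, 0.57 in normoxia and -0.26 in hypoxia. DNA replication genes had a median of -0.48, below each of the 10000 random lists, with 25 of 28 below 0 and none called. PCNA, the replication clamp, was at -1.16 and the helicase gene MCM6 at -1.14. Cholesterol synthesis genes had a median of -0.33, with 14 of 17 below 0. Their 2 pairs differed in size, at -0.05 in normoxia and -0.59 in hypoxia.

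NRF2 targets had a median of 0.45 (percentile 97.4), with PGD of the pentose phosphate pathway called higher (1.18) and NQO1 (0.97) short of the threshold in hypoxia. The noncoding hosts of small nucleolar RNAs had a median of 0.80 (percentile 99.99), with SNHG8 called higher (1.26) and the monosome-confined GAS5 at 0.97. Among heat shock genes HSP90AB1, a cytosolic chaperone, was called higher (1.56), while the list median was 0.07, or 0.026 under the authors' RNA scaling. Acid and base transport genes (7 measured) had a median of -0.06 (0.16 in normoxia and -0.36 in hypoxia), or 0.00 without centring, and 13 proton pump (V-ATPase) genes one of -0.16, with 0 called in either list.

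Over all loci, 149 were higher and 29 lower with acidosis, where unrelated pairs would give 24.4 and 10.0. Under the authors' RNA scaling the counts were 194 and 81. Across loci, which are not independent replicates, the 2 pairs had r = 0.335 and rho = 0.407, with a covariance of 0.132. Simulated fragments with counting error alone gave r = -0.31 and a covariance of -0.00554.

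Hypoxia came with higher mRNA of the genes that hypoxia-inducible factors are known to activate. IGFBP3, a binding protein of insulin-like growth factors (chromosome 7, 45912245 to 45921874), had an aggregate of 6.46 FPKM in normoxia and 314 FPKM in hypoxia at pH 7.4, and of 5.71 and 305 FPKM at pH 6.0 (mean 43.3-fold). F3, tissue factor, was 25.1-fold higher, NDRG1 16.2-fold, the collagen crosslinking enzyme gene LOX 15.2-fold, and SLC2A1, the glucose transporter GLUT1 (chromosome 1, 42925375 to 42959176), 10.2-fold. ODC1, which makes putrescine for polyamine synthesis, was lower (log2 -2.12 at pH 7.4 and -1.35 at pH 6.0), as was AEN, a p53-induced nuclease (-1.25 and -3.10).

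Further genes with higher mRNA were PPP1R3C of glycogen synthesis (3.55), C10orf10 (3.53), ANGPTL4 (3.21), ICAM5 (2.93) and ADM, adrenomedullin (2.87; chromosome 11, 10304680 to 10307397). CA9, the extracellular carbonic anhydrase IX (chromosome 9, 35673856 to 35681159), had log2 changes of 3.24 and 2.19, and VEGFA (chromosome 6, 43770184 to 43786487) of 2.22 and 1.55. TNFRSF21 (-2.001), LSM10 (-1.83), TMEM138 (-1.76), PNO1 (-1.74) and EREG, the growth factor epiregulin (-1.73), were lower. FCHO2, PURB and RANBP3L were also called lower and were monosome-confined.

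All 20 measured hypoxia targets lay above 0 and 15 were called higher (median 2.32, percentile 100). Of 10 glycolysis genes, 6 were called higher (median 1.83, percentile 100), among them HK2, a hexokinase (2.23), PFKP, a phosphofructokinase (1.99), and GAPDH (2.34), whose many pseudogenes make its level uncertain. Matrix and mesenchymal genes followed, with 7 of 20 called higher (median 1.07, percentile 100), including TGFBI (2.40), COL1A2 of collagen I (2.08) and VIM, vimentin (2.06). Lysosome and autophagy genes had a median of 0.70 (percentile 99.95) with none called, and one of 0.37 under the authors' RNA scaling. The progranulin gene GRN (1.13) and the autophagy kinase gene ULK1 (1.13) led the list. ULK1 passed 2-fold in both pairs (1.09 and 1.16), but a call also asks for the same direction in each fraction.

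DNA replication genes had a median of -0.46 (percentile 0.02) with 3 of 28 called lower, PCNA (-1.32) and E2F1 (-1.26) among them. DNA repair genes had a median of -0.50 (percentile 0.15) with XRCC2 called lower (-1.27). Targets of p53 had a median of -0.40 (percentile 0.41), which was 0.07 at pH 7.4 (-0.28 under the authors' RNA scaling) and -0.64 at pH 6.0, with AEN (-2.17) and TIGAR (-1.64) called lower. Under the same scaling the 3 list medians were -0.83, -0.92 and -0.77. In the list of eIF5A and mTORC1 regulators DDIT4 (REDD1), an inhibitor of mTORC1, was called higher (1.76).

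Over all loci, 263 were higher and 111 lower with hypoxia, where unrelated pairs would give 40.5 and 25.5. Under the authors' RNA scaling the balance was the other way, with 182 higher and 373 lower. The 2 pairs had r = 0.483 across loci and a covariance of 0.256, against r = 0.158 and a covariance of 0.00353 with counting error alone.

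**Figure D2:**
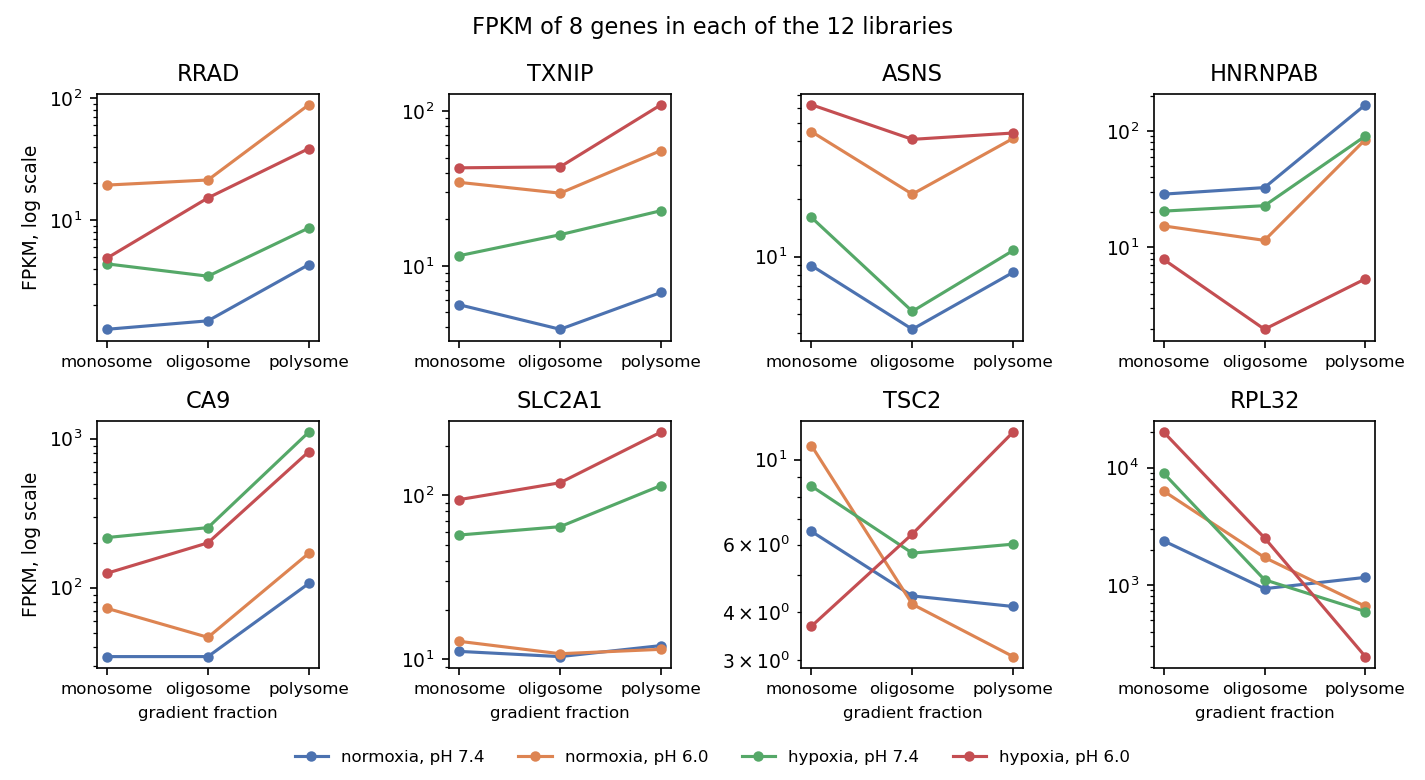
FPKM (log scale) of 8 genes in the monosome, oligosome and polysome libraries (horizontal axis), with 1 line per condition. CA9 and SLC2A1 lie higher in both hypoxic conditions in each fraction, while RPL32 lies higher in the monosome library and lower in the polysome library of every stress than in normoxia.

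With acidosis, most ribosomal protein mRNAs were lower in the polysome relative to the monosome fraction. Their median TE ratio was 0.398 in normoxia and 0.0778 with acidosis. In hypoxia it was 0.0685, and with acidosis 0.0335. The list median of the log2 TE change was -1.61, below each of the 10000 random lists, with 38 of 59 genes called lower and 0 higher. RPLP0 (0.59), RPSA (0.58) and RPL41 (0.09), all monosome-confined, lay above 0. RPL3 was among those above 0 with acidosis in hypoxia (1.77). RPL32 (chromosome 3, 12834485 to 12841588) was at -2.30, RPL12 at -2.26, RPS7 at -2.12 and RPL21 at -2.08. These 4 genes have 12, 50, 15 and 66 annotated pseudogenes that can share their reads, so their single levels are uncertain.

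Translation factors, which start, extend and end protein synthesis, had a median of -0.46 (percentile 8.59) with 6 of 31 called lower, among them the initiation factor subunit genes EIF3H (-1.76) and EIF3M (-1.34). ER chaperones had a median of -0.82 (percentile 0.16), with CALR, calreticulin (-1.16), HSPA5, BiP (-1.02), and SEL1L (-1.004) called lower. Acid and base transport genes had a median of -0.66 (percentile 1.78), with the carbonic anhydrase gene CA13 (-1.66) among 2 of 7 called lower. Lysosomal membrane proteins LAMP1 (-0.92) and LAMP2 (-1.38) were among those called lower in a list of median -0.15 (-0.0060 under the authors' RNA scaling). MAP1LC3B (0.75) and GABARAPL2 (0.86) of the same list were called higher. Cholesterol synthesis genes had a median of -0.39 (percentile 2.3), with HSD17B7 (-1.02) among those called lower.

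Higher TE with acidosis was seen for DDIT3 (CHOP), a transcription factor of the integrated stress response (chromosome 12, 57516588 to 57521737), at 1.36, with TE ratios of 0.348 in normoxia and 0.529 with acidosis, and of 0.214 in hypoxia and 0.892 with acidosis. ATF4 itself (chromosome 22, 39519695 to 39522685) had log2 TE changes of 0.11 in normoxia and 1.42 in hypoxia, and was not called. Of 22 genes in the ATF4 list 4 were called higher and 1 lower, and the list median was 0.24 (percentile 94.0), or 0.40 under the authors' RNA scaling. Its pairs differed, at 0.03 in normoxia and 0.60 in hypoxia. CDKN1A was called higher (1.33), as were 3 polyamine genes, OAZ2, an antizyme (1.71), SAT1, which acetylates polyamines (1.03), and SMOX (0.81), whereas AMD1, which supplies the aminopropyl donor, was called lower (-1.51).

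By size, the genes of highest TE change were MANBAL (2.15), KLC4, a kinesin light chain (2.01), POMGNT1 of mannosyl glycan synthesis (2.01), TMEM183A (1.98), CCDC150 (1.97), PKIG (1.93) and KIAA1191 (1.93), with FSCN1 and PTCHD3P1 monosome-confined. The histone gene HIST1H3F was also among the 10 and was listed at 0 in the monosome library of both acidosis conditions. The genes of lowest TE change were IRX3, listed at 0 in the monosome and polysome libraries of normoxia, and GPR174 (-2.68), RPL22L1, a paralog of a ribosomal protein gene (-2.60), UTP11L (-2.56), NUCKS1 (-2.52), TMEM33 (-2.47), ACOX2 (-2.43) and DPH6 (-2.41), with the pseudogenes RPS20P10 and RPL12P4 (-2.38). With TE taken as polysome over oligosome, an alternative chosen after the values were seen, NUCKS1 stood at 0.071.

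Over all loci, 698 had higher and 814 lower TE with acidosis, where unrelated pairs of equally variable loci would give 510 and 580. Loci differ in their error, so this excess need not show that the pairs agree. The authors' RNA scaling gave 1482 higher and 582 lower. The 2 pairs had r = 0.106 across loci and a covariance of 0.0948, against -0.000132 with counting error alone. For TE, acidosis, correlation of the 2 pairs was -0.0768 when the ratio was taken as oligosome over monosome.

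With hypoxia, the median TE change of ribosomal protein and respiratory chain mRNAs lay below 0 and that of glycolytic, matrix and immediate-early mRNAs above 0, relative to the median locus. Ribosomal protein genes had a median log2 TE change of -1.90, with 42 of 59 called lower and 0 higher, and RPL32 (-2.92), RPS7 (-2.77) and RPL27 (-2.57) at the far end. Nuclear genes of oxidative phosphorylation had a median of -1.02 (percentile 0.07; -0.70 and percentile 8.29 at pH 7.4, -1.29 and percentile 0 at pH 6.0), with 24 of 48 called lower and 1 higher. COX5A, a subunit of cytochrome c oxidase (-2.37), UQCRB of complex III (-2.21) and ATP5PD (-1.998) and ATP5F1D (-1.84) of ATP synthase were the largest. The gene called higher was SDHA (1.69). The random lists were not matched on transcript length, so a bias by length was not tested for this list. Glycolysis genes had a median of 1.00 (percentile 100), with 5 of 10 called higher, HK1 (1.86), SLC2A1 (1.26) and PFKP (1.18) among them, and GAPDH called lower (-1.26). Under the authors' RNA scaling the medians of oxidative phosphorylation and glycolysis genes were -1.65 and 0.41.

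Matrix and mesenchymal genes had a median of 0.88 (percentile 100) and 9 of 20 were called higher, with COL6A1 of collagen VI at 1.86 and COL1A1 at 1.37. Immediate-early genes had a median of 0.98 (percentile 100) and 8 of 16 were called higher, with EGR1 at 2.35, JUNB at 1.99, the phosphatase gene DUSP1 at 1.67 and JUN at 1.55. Under the authors' RNA scaling the matrix and immediate-early medians were 0.21 and 0.61. ER chaperones had a median of 0.57 (percentile 99.85; 0.02 under the authors' RNA scaling), with HSPA5 (1.58), PDIA3 (1.21) and PDIA4 (1.09) among 4 called higher. Hypoxia targets had a median of 0.43 (percentile 99.95) with 6 of 20 called higher, including NDRG1 (1.61) and LOX (1.29). ANGPTL4 (1.92) was also called, but its aggregate was 0.40 FPKM in normoxia and 0.30 FPKM with acidosis, where the pseudocount largely sets the TE ratio. The list median was -0.17 under the authors' RNA scaling. The lysosome list had a median of 0.46, or -0.14 under that scaling, with PSAP (1.56) and TPP1 (1.35) called higher. ATF4 was lower in TE at pH 7.4 (-1.23) and close to the median locus at pH 6.0 (0.05).

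Among single genes, ZC3H3 (2.92), PCCA, a subunit of propionyl-CoA carboxylase (2.71), EGR1 and the pseudogene USP8P1 (2.87) had the highest TE changes outside the monosome-confined loci RSL24D1P1, FCHO2, PLCB1, PURB, FSCN1 and DYM. The lowest changes were those of RPL32, RPS7, RPL22L1 (-2.90) and SPIDR, listed at 0 in several libraries, and of 6 pseudogenes, TMSB10P1, RPS21P4, RPS7P11, RPL35P2, MT1P3 and RPS7P10. Of these pseudogenes, TMSB10P1, RPS21P4 and MT1P3 were listed at 0 in at least 1 library.

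Over all loci, 1070 had higher and 1229 lower TE with hypoxia, where unrelated pairs of equally variable loci would give 651 and 756. As with acidosis, unequal error among loci can give part or all of this excess. Of the 1070 loci, 428 were monosome-confined. The authors' RNA scaling gave 446 higher and 3306 lower. The 2 pairs had r = 0.292 across loci and a covariance of 0.348, against -0.00017 with counting error alone.

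**Figure D3:**
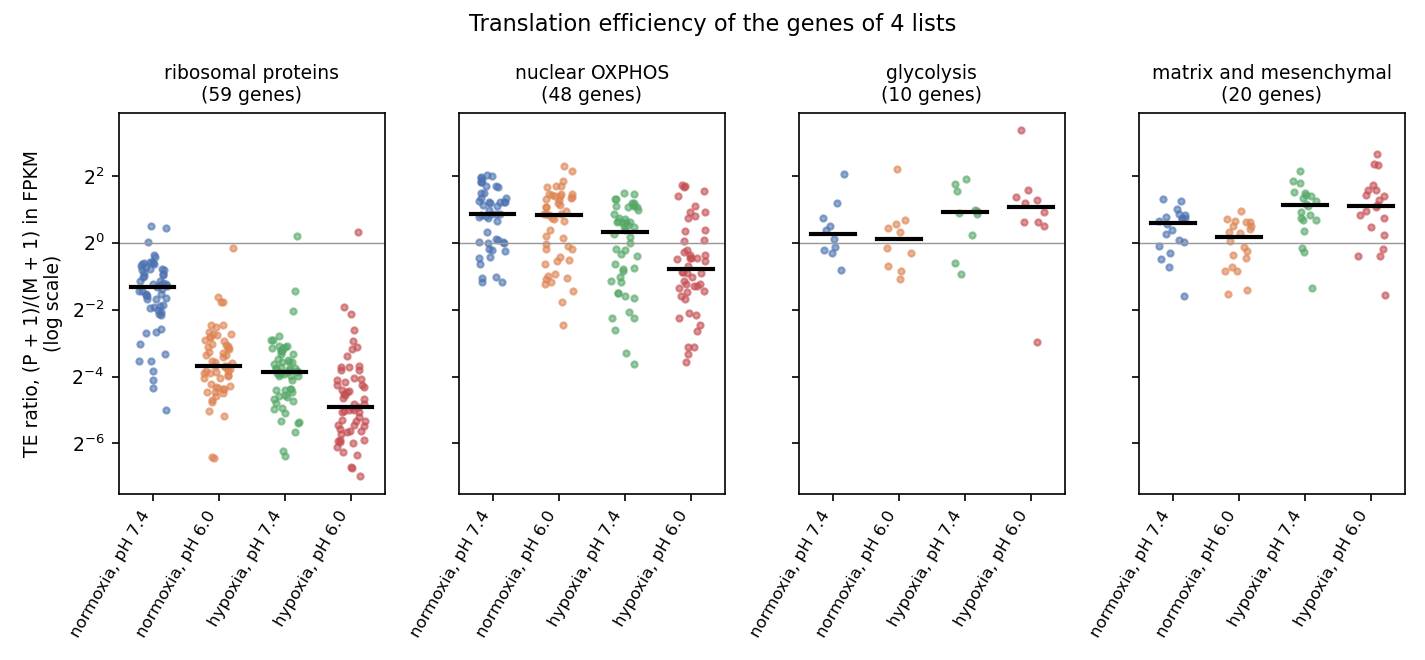
TE ratio (log scale) of each measured gene of 4 lists (points) in the 4 conditions, with the list median as a bar. The median of 59 ribosomal protein genes was 0.398 in normoxia and 0.0335 in hypoxia with acidosis, and that of 10 glycolysis genes 1.19 and 2.09.

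**Figure D4:**
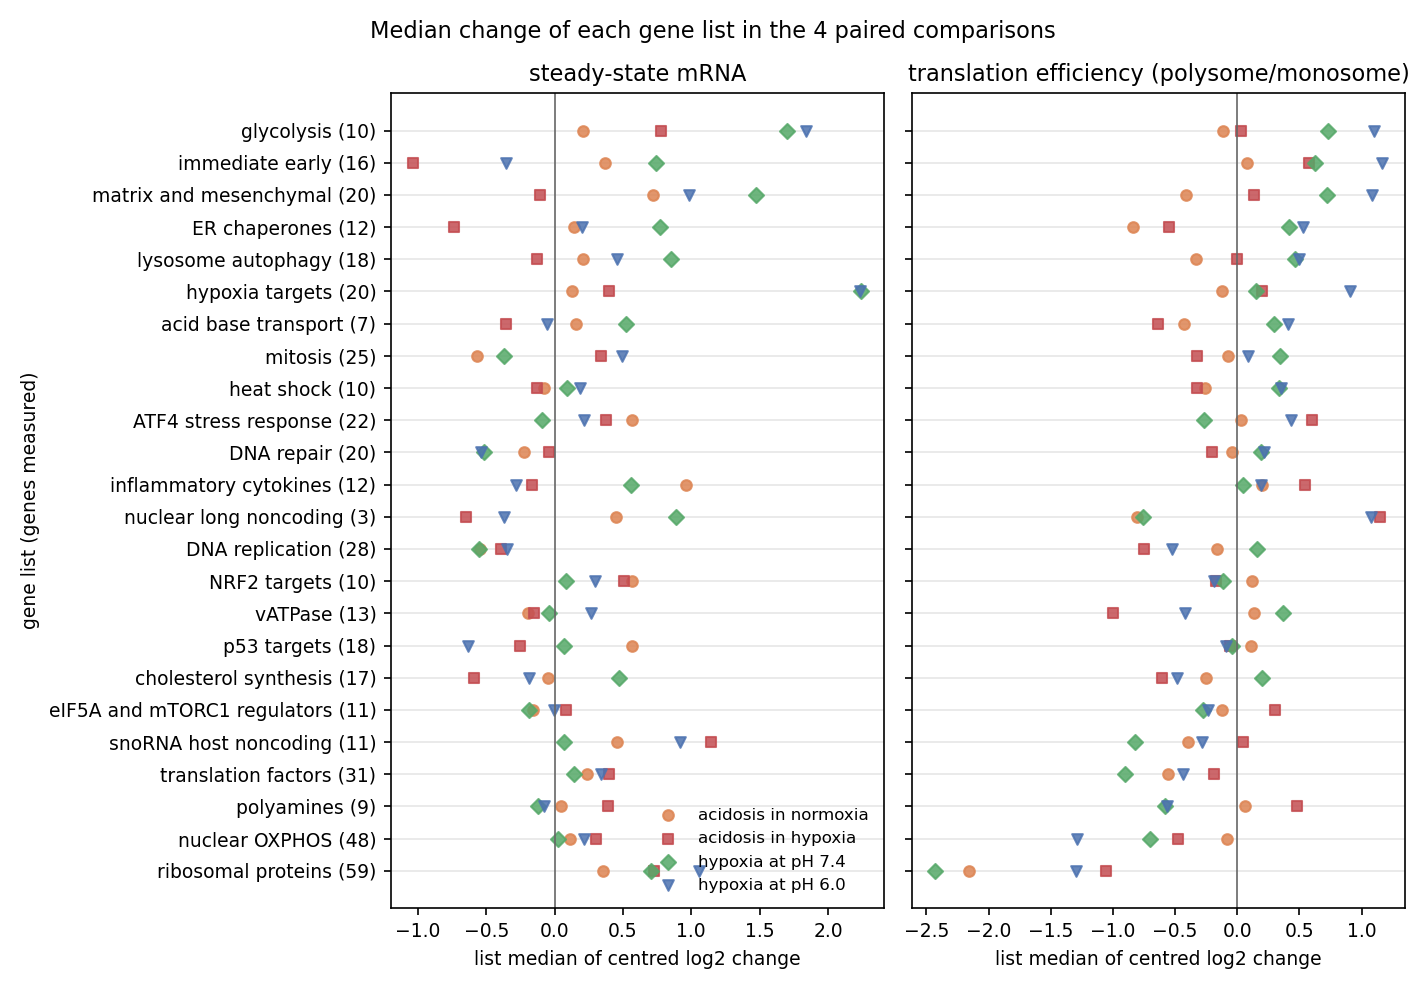
Median centred log2 change (horizontal axis) of each gene list (vertical axis, genes measured in brackets) in steady-state mRNA (left) and TE (right), with 1 symbol for each of the 4 paired comparisons. Ribosomal proteins lie at -2.16 and -1.06 for acidosis and at -2.44 and -1.29 for hypoxia in TE.

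In hypoxia with acidosis, set against normoxia, genes known to respond to hypoxia were among the highest in steady-state mRNA. PPP1R3C was 39.3-fold higher, IGFBP3 38.7-fold, LOX 33.3-fold and C10orf10 32.8-fold. CDKN1C, the cell cycle inhibitor p57 (chromosome 11, 2883213 to 2885773), was at 0.125 FPKM in normoxia, 0.392 FPKM with acidosis, 1.04 FPKM in hypoxia and 41.3 FPKM with both. HNRNPAB was the lowest named gene outside the monosome-confined loci, with 101 FPKM in normoxia and 5.09 FPKM with both stresses. NSUN4 and C6orf52, both monosome-confined, were listed at 0 in every library but the monosome library of normoxia.

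Of 20 hypoxia targets 18 were called higher in steady-state mRNA (median 2.57), as were 8 of 10 glycolysis genes (2.14) and 12 of 20 matrix genes (1.33). DNA replication genes had a median of -0.98, with 14 of 28 called lower and 2 higher, PCNA (-2.48) and GINS1 (-2.08) among them. In TE, 53 of 59 ribosomal protein genes were called lower and 2 higher (median -3.55), with RPL22L1 outside the list at -5.54, RPL32 at -5.26 and RPS7 at -4.92, and the pseudogenes RPS7P11 at -5.03 and RPS19P1 listed at 0 in the polysome library of each stress. Of 48 oxidative phosphorylation genes 37 were called lower and 3 higher (median -1.25, percentile 1.55), with COX5A at -4.28. The 5 highest TE changes were those of NSUN4, C6orf52, RSL24D1P1, PLCB1 and FSCN1, all monosome-confined, and among immediate-early genes 13 of 16 were called higher (median 1.26), with EGR1 at 3.49. In steady-state mRNA the median of immediate-early genes was -0.45 and EGR1 was at -1.99, so a higher ratio does not mean more of the mRNA on polysomes.

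Over all loci, 1457 were higher and 1527 lower in steady-state mRNA, and 3390 higher and 3635 lower in TE. Under the authors' RNA scaling the counts were 999 and 2557 for steady-state mRNA and 2435 and 5388 for TE.

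PHGDH (1.23 with acidosis and 1.47 with hypoxia) and HSP90AB1 (1.56 and 1.41) were among the genes called higher in steady-state mRNA with each stress. Ribosomal protein genes had median steady-state changes of 0.58 and 0.86 (percentile 100 in each; 0.49 with hypoxia under the authors' RNA scaling), although 0 of 59 were called and their reads are partly shared with pseudogenes. Their median TE changes were -1.61 and -1.90, so the monosome fraction rose relative to the polysome fraction. The aggregate values therefore do not show higher mRNA of these genes in each fraction. Across loci, the correlation of both effects was 0.472 for steady-state mRNA and 0.304 for TE, against -0.0174 and 0.0761 in simulated fragments with no effect. The covariances were 0.154 and 0.192, against -0.000168 and 0.00334. The simulation holds counting error alone, while both effects use the same libraries, so part of the excess may come from differences between single libraries.

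TSC2, a brake on mTORC1 (chromosome 16, 2047465 to 2089487), had TE ratios of 0.686 in normoxia, 0.342 with acidosis, 0.737 in hypoxia and 2.73 with both, at 4.31 to 8.87 FPKM in aggregate. EIF5A, the hypusinated translation factor (chromosome 17, 7306999 to 7312463), had TE ratios of 2.62, 3.09, 2.03 and 1.53 in the same order, and its aggregate was 539, 369, 334 and 227 FPKM. SIRT1 (chromosome 10, 67884669 to 67918390) is named by 2 loci, of which one was at 2.52 to 3.31 FPKM in every aggregate with TE ratios of 1.61 to 2.08, and the other was monosome-confined. MTOR was measured together with a small nucleolar RNA name in a shared locus, with polysome FPKM of 3.26, 2.64, 2.53 and 1.74 and monosome FPKM of 2.37, 2.52, 1.16 and 0.459 in the same order. The acidosis change in normoxia and that in hypoxia were at least 2-fold apart for 1538 loci in steady-state mRNA and 4302 in TE, which was not tested and includes any difference between single libraries.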

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

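The tests of a fault in a single library and of terminal oligopyrimidine mRNAs in each stress alone, the estimate of counting noise from fragment numbers, and the depth test in hypoxia at pH 6.0 were chosen after the results were seen. The depth test at pH 7.4 was set beforehand and its value met the bound that counts against lower depth, but it was judged void, and its verdict changed to open, after that value was seen. Opposite signs of the acidosis change in normoxia and in hypoxia were common. They are listed here where both sides reached 0.3 on the log2 scale for a list median, or 0.5 for the 12 genes fixed beforehand outside monosome-confined loci, limits chosen after the values were seen. The difference was not tested for any of them. For steady-state mRNA, the median of mitosis genes was -0.56 in normoxia and 0.34 in hypoxia, a difference of 0.90. The median of immediate-early genes was 0.37 and -1.03, a difference of -1.40. For 3 nuclear long noncoding RNAs (NEAT1, TUG1 and MEG3) the median was 0.45 and -0.65, a difference of -1.10, and in TE it was -0.80 and 1.15, a difference of 1.95. The TE medians came from different genes: NEAT1, monosome-confined, had -0.11 and 3.35, TUG1 -0.80 and -0.059, and MEG3, at a mean of 1.27 FPKM, -0.90 and 1.15. HMGCS1, the synthase at the start of the sterol pathway, had 0.50 and -0.91 in steady-state mRNA, a difference of -1.41. TSC2 had -0.95 and 1.90 in TE, a difference of 2.86.

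Ribosomal protein mRNAs had a median log2 TE change of -3.55 in hypoxia with acidosis against normoxia. A bias against short abundant mRNAs is argued against as the whole cause, since 34 other genes matched on length and FPKM had a median of -0.75. That median was itself below the median locus, so such a bias stays open as a part of the shift. The FPKM of the matched genes was also lower (median 1179 against 2719). Reads shared with pseudogenes are argued against as the whole cause, with -3.09 in the 20 genes with the fewest pseudogenes, and so is a fault of the monosome library of hypoxia with acidosis, with -2.16 as the value nearer 0 of the 2 comparisons without it. A candidate explanation is regulation of mRNAs with a terminal oligopyrimidine tract: the median of other such mRNAs minus that of matched genes was -1.25 in the stress alone where it lay nearer 0, but -0.96 with both stresses, where PABPC1 (2.71) and EEF2 (1.08) went the other way, which left that comparison undecided. With 1 library per group, a difference between gradients or cultures stays open as well.

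The monosome-confined loci (1134, of which 740 name no gene) made up 428 of the 1070 loci called higher in TE with hypoxia, which their choice by a high monosome FPKM in normoxia itself favours. Lower depth of the hypoxia monosome library stays open: the median log2 monosome change of these loci minus that of other loci of equal monosome FPKM was -1.56, more than 1 below 0 as the bound asked, but this comparison uses the library by which they were chosen. In hypoxia at pH 6.0, which does not use it, the same difference was -0.45 (resampling spread 0.050), which decides neither way. Small RNAs inside the named genes could be the source, with 2.17 times the share of other loci, but 162 of the loci (14.3%) name 1 annotated gene, too few for the test to decide. No biological explanation was tested for these loci.

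The log2 TE change by acidosis was spread wider in hypoxia (SD 1.23) than in normoxia (SD 0.954) over 4979 loci with a mean FPKM of at least 10. Counting noise may be part of this, as the SD ratio was 1.29 over these loci and 1.05 over those with a mean FPKM of at least 100. The latter hold most ribosomal protein genes, whose median TE change by acidosis was -2.16 in normoxia and -1.06 in hypoxia. The lower ratio there need not come from less noise. The SD that counting error adds was estimated at 0.0778 against an excess of 0.766, which points away from counting noise, but this sets a spread between single libraries against technical noise and decides nothing. A fault of the monosome library of hypoxia with acidosis cannot be told apart from the others, since the SD ratio of 1.24 in the polysome libraries lay within its resampling spread (0.0558) of the bound set. A difference in the response to acidosis between oxygen levels stays open and untested, since each SD rests on single libraries.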

How the results depend on the processing

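The alternatives that removed monosome-confined loci or loci with a possible failed 0, used the authors' RNA scaling without centring, took TE as polysome over oligosome, or gave list medians with another centring or with small and antisense transcripts kept were chosen after the data were seen. No paired analysis was possible because there are no replicates to pair, with 1 library per condition and fraction. The pairs of conditions were compared by size, without a test. Among alternatives fixed beforehand, 103 counts stayed within 1.5 times and 30 did not, 51 correlations stayed within 0.1, 5 lay further off and 1 changed sign, 254 list medians stayed within 0.2 and 34 did not, and for named genes 1210 stayed within 0.2, 376 did not and 2 changed sign. For alternatives added later these were 39 and 10 counts, 18 and 3 correlations, 786 and 144 list medians, and 366, 190 and 8 values of named genes. Depth limits loci near 1 FPKM, where counting error alone gives an SE of 0.70 for a TE difference.

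With a pseudocount of 0.1, for steady-state mRNA, acidosis, genes higher numbered 262 and lower 93, for steady-state mRNA, hypoxia, genes higher numbered 397 and lower 241, and for steady-state mRNA, genes whose acidosis effect differs by oxygen numbered 2532. A mean FPKM of at least 5, which leaves fewer loci to count, gave 94 higher with acidosis, 168 higher with hypoxia and 878 that differed by oxygen, and for steady-state mRNA, hypoxia with acidosis against normoxia, genes lower numbered 988 and higher 853. With monosome-confined loci removed, the acidosis pairs had r = 0.45. The authors' RNA scaling gave 81 lower with acidosis, 373 lower with hypoxia and 2557 lower with both. Without the monosome fraction, r was 0.463 for acidosis and 0.584 for hypoxia. Without the polysome fraction, 54 were lower with acidosis, 410 higher with hypoxia (r = 0.372) and 2461 differed by oxygen, and for steady-state mRNA, hypoxia with acidosis against normoxia, genes higher numbered 2259. TSC2 stood there at -0.064 with both stresses, against 0.74 with the 3 fractions. Except for the fewer loci, the cause was not tested.

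With a mean FPKM of at least 5, for TE, acidosis, genes higher numbered 429, for TE, acidosis, genes lower 540, for TE, hypoxia, genes higher 677, for TE, hypoxia, genes lower 781, for TE, hypoxia with acidosis against normoxia, genes higher 2189, for TE, hypoxia with acidosis against normoxia, genes lower 2281, and for TE, genes whose acidosis effect differs by oxygen 2620. The authors' RNA scaling gave 1482 higher with acidosis, and 446 higher and 3306 lower with hypoxia. Oligosome and polysome over monosome gave 460 higher and 528 lower with acidosis. Polysome over monosome and oligosome gave 332 higher with acidosis, 552 higher and 725 lower with hypoxia, r = 0.517 between the effects of acidosis and hypoxia and 2590 that differed by oxygen, and EIF5A stood at 0.070 with both stresses. With oligosome over monosome, 320 were higher and 381 lower with acidosis, 664 were higher with hypoxia, r was 0.132 between the effects, and for TE, acidosis, correlation of the 2 pairs was -0.0768. Polysome over oligosome gave 350 higher with acidosis (r = 0.27), 421 higher and 536 lower with hypoxia, r = 0.451 between the effects and 1720 that differed by oxygen. Under it the sign was the other way for FSCN1 (-0.83 with acidosis, -0.84 with both), NUCKS1 (0.071 with acidosis), MT1P3 (0.39 with hypoxia), and with both stresses EIF5A (0.42), the monosome-confined SIRT1 locus (-0.13) and ADM (-0.11), and for TE, hypoxia, ATF4 (XLOC_035308) stood at 0.0083. Except for the fewer loci, the cause was not tested.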

Other observations

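Genes of inflammatory signalling and of translation gave values not described above. The 12 measured inflammatory cytokine genes had a median steady-state change of 0.51 with acidosis (percentile 99.9), with none past both thresholds. The pairs differed, at 0.96 in normoxia and -0.17 in hypoxia, and CXCL8, the chemokine interleukin 8, had 2.39 and -0.94. These differences were not tested. With both stresses, 6 of the 12 were called higher in TE (median 0.54, percentile 92.5, within the range of matched random lists), among them TNFAIP3, an inhibitor of NF-kB signalling (1.95), and LIF (1.06). IL1A, IL1B, LIF and IL24 among these lay at a mean of 1.27 to 1.835 FPKM. At 1 FPKM counting error alone gives an SE of 0.70. The noncoding hosts of small nucleolar RNAs had a median of 1.21 in steady-state mRNA with both stresses, with 6 of 11 called higher. ZFAS1 (1.95) and GAS5 (1.56), both monosome-confined, were among them. Their median TE change was -0.49, and ZFAS1 was called lower in TE (-2.64). SNHG15 went the other way, at -1.375 in steady-state mRNA and 1.18 in TE.

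Some abundant mRNAs with a terminal oligopyrimidine tract, named here after their values were seen, went different ways in TE with acidosis in normoxia and in hypoxia. EEF2, the elongation factor that moves the ribosome, had -1.14 and 2.18, EEF1A1 -1.71 and 1.15, and EIF3F -1.89 and 1.34. PABPC1, the poly(A)-binding protein, had -0.56 and 2.23, and EEF1B2 -1.98 and 0.42. The difference was not tested, and these genes have pseudogenes or related copies that can share reads. In the same comparisons TPT1 had -2.03 and -2.31, EIF3H -2.001 and -1.52, EIF2S3 -1.65 and -0.52, and GNB2L1 -2.03 and -0.14, while NAP1L1 and EEF1D were near 0 in hypoxia (0.062 and 0.061). Among 31 translation factors, 8 passed the TE threshold upward and 11 downward with acidosis in hypoxia. With both stresses, 19 of these 31 were called lower and 5 higher in TE (median -0.98, percentile 9.48, within the range of matched random lists), with EIF3H at -3.79. Of 13 proton pump (V-ATPase) genes, 8 were called lower and 2 higher (median -0.68, percentile 10.5, also within that range; -1.25 under the authors' RNA scaling), with ATP6V1F at -2.32. In polyamine metabolism with both stresses, AMD1 was lower in steady-state mRNA (-2.70) and in TE (-2.16), while SAT1 was higher in steady-state mRNA (1.94).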
